A study of Rattus norvegicus with 8 samples.

How the data were processed

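RNA was measured by sequencing in 8 rat liver libraries, 2 in each of 4 groups of a 2 by 2 design: control, atorvastatin, hexachlorobenzene (HCB), and atorvastatin plus HCB. Per the labels, each library comes from a separate rat. The deposited table holds whole-number read counts for 30562 Ensembl genes, and a deposited summary holds the number of reads in each assignment class of the counting tool. Per the submitters' processing notes, reads were trimmed with fastp 0.23.4 and aligned with STAR 2.7.10b. Per the file headers, they were counted over exons with featureCounts 2.0.6 against Ensembl release 111 of the mRatBN7.2 build, with no strand option and no option for multimapping reads. Per the submitters' processing notes, the authors used DESeq2 1.42.1 in R 4.3.2 for their own tests. The count table and its summary were used, and 0 of their columns were left out. All coordinates are those of the table, on mRatBN7.2.

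The reads of all assignment classes add up to 508 M over the 8 libraries, 2.04 times the 249 M that the notes state, and per the file headers the counting command has no option to count read pairs, so the mates of a pair appear to have been counted singly in the deposited counts. Assigned reads ranged from 29.4 M to 52.0 M (M, reads in units of 1e6) per library. A gene with 0 reads in a group was set at a floor of 6 reads, or 3 read pairs, over the group's libraries, and folds against such a group are lower bounds from that floor. Floors and intervals cover counting error only.

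Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalisation, filterByExpr on the 4 groups, and the quasi-likelihood test with robust estimation in 1 model of 4 groups, which left 4 residual degrees of freedom. The filter kept 16591 genes, and 4367 genes of the table have no symbol. Gene p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and 0.05 was the threshold. The common biological coefficient of variation was 0.295. Levels are in CPM, counts scaled to normalised library size, with a prior count of 2 for log values, and log2 fold changes carry their standard error (SE). The contrasts were each treatment against control, the combination against each single treatment and against control, the interaction, and the average effect of each treatment. All contrasts share 1 estimate of the spread.

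A set of 36 gene lists with 575 symbols, of which 552 were found among the annotated genes, was tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01. List p-values were adjusted by the Benjamini-Hochberg method over the lists of a comparison. Camera with an estimated correlation and fry stood beside it. Member counts are given over all genes tested and adjusted over the list alone. The lists, the tests, the rule for naming genes and the main alternatives were fixed before the data were examined. A further 2 lists, of Y-linked genes and of imprinted growth genes, were added afterwards.

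The rule named 14 genes in any case, not all of which are reported here. It also named, per comparison, up to 8 genes with the largest rise and 8 with the largest fall among genes past the threshold that have a name, do not overlap between the groups, and reach 1 CPM in the higher group. Where fewer than 5 genes passed, it named the 5 with the smallest p. From each list it named up to 4 members past the threshold with the smallest p, or up to 2 where none passed. Genes outside the rule are said to be chosen after their values were seen.

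Both comparisons that share the HCB libraries were set beside 20 simulated draws that share libraries in the same way. The steps were tested on simulated counts for 16591 genes. Of 100 genes changed 4-fold, 69 were recovered in HCB versus control, 57 in atorvastatin versus control and 61 in atorvastatin plus HCB versus HCB. Of 100 genes changed 2-fold, 8, 10 and 1 were recovered in these comparisons. The false calls were 6, 13 and 5. For the average effect of atorvastatin, 78 of 100 genes changed 4-fold and 48 of 100 changed 2-fold were recovered, with 12 false calls among 138.

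The alternatives were DESeq2 1.42.0, its size factors in the edgeR model, no filter on low counts, a stricter filter of 1 CPM in 2 libraries, estimation without robustness, a replicate block, the libraries of 2 groups alone, and each library left out in turn. Chosen after the data were seen were halved counts, the removal of both libraries with most reads outside exons, the removal of genes on chromosome Y, and DESeq2 with the filter of the deposited readme (5 counts in 3 libraries, log2 change over 2 in size). Data were handled with version 1.17.8 of data.table, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

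Counting used no strand, so a gene and an overlapping antisense gene cannot be told apart, and near-identical genes share reads. This bears on the Cyp2b, Cyp2c, Gsta, Mup and alpha globin families, and on Mup4, whose annotated span overlaps Obp3.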

Results

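The data are read counts per gene from the livers of 8 rats labelled as male Wistar animals of 160 g. Per the labels, 20 rats were assigned to 4 groups of 5, and 2 per group were sequenced with 150 bp paired reads. HCB, a chlorinated fungicide and persistent pollutant that causes porphyria and liver tumours in rodents, was given by gavage at 100 mg/kg 3 times a week for 30 days. Atorvastatin, a statin that inhibits cholesterol synthesis, was given in drinking water at a stated 5 mg/kg per day, and the rats were killed on day 37. The water recipe in the same labels, 5 mg in 20 mL per rat and day, amounts to 31.25 mg/kg at the stated weight, so the dose received is uncertain. Assigned reads were 30.2 M and 41.9 M in the control libraries, 29.4 M and 43.8 M in the atorvastatin libraries, 38.4 M and 42.1 M in the HCB libraries, and 51.4 M and 52.0 M in the libraries of both treatments. The share of reads in no annotated exon was 27.7% and 15.3% in control, 34.04% and 19.5% in atorvastatin, 10.8% and 11.4% in HCB, and 7.46% and 9.48% in the combination. The first principal component of log CPM held 72.1% of the variance and separated the libraries by HCB. Across genes, which are not independent replicates, libraries of the same HCB status correlated at 0.960 to 0.982 and libraries of different status at 0.856 to 0.906.

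Genes of chromosome Y did not follow the labels, which call every rat male. Ddx3, the Y-linked helicase of the table, averaged 76.1 ± 14.2 CPM (SD, n = 4) in the libraries labelled HCB or atorvastatin plus HCB and 0.291 ± 0.237 CPM (SD, n = 4) in those labelled control or atorvastatin. The histone demethylase Kdm5d averaged 25.9 ± 1.12 against 0.315 ± 0.127 CPM, the translation factor Eif2s3y 33.6 ± 12.9 against 0.427 ± 0.115 CPM, and the histone demethylase Uty 24.7 ± 10.4 against 0.359 ± 0.188 CPM. These 4 genes were chosen after their values were seen. Each stood at 0.383% to 1.45% of its level in the HCB-labelled libraries. In HCB versus control all 5 Y-linked genes tested rose, with a median log2 change of 6.35, and 7 of 8 imprinted growth genes fell, with a median of −3.08, Grb10 and Mest among them (lists made after the data were seen). The same libraries held the fetal serum protein Afp at 20803 ± 12647 CPM (SD, n = 2) in control and 17794 ± 9022 CPM in atorvastatin, against 108 ± 53.3 CPM in HCB and 77.7 ± 10.5 CPM in the combination. Every direction given for HCB is therefore a difference between libraries labelled as exposed, with Y-linked expression, and libraries labelled as unexposed, nearly without it.

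**Figure D1:**
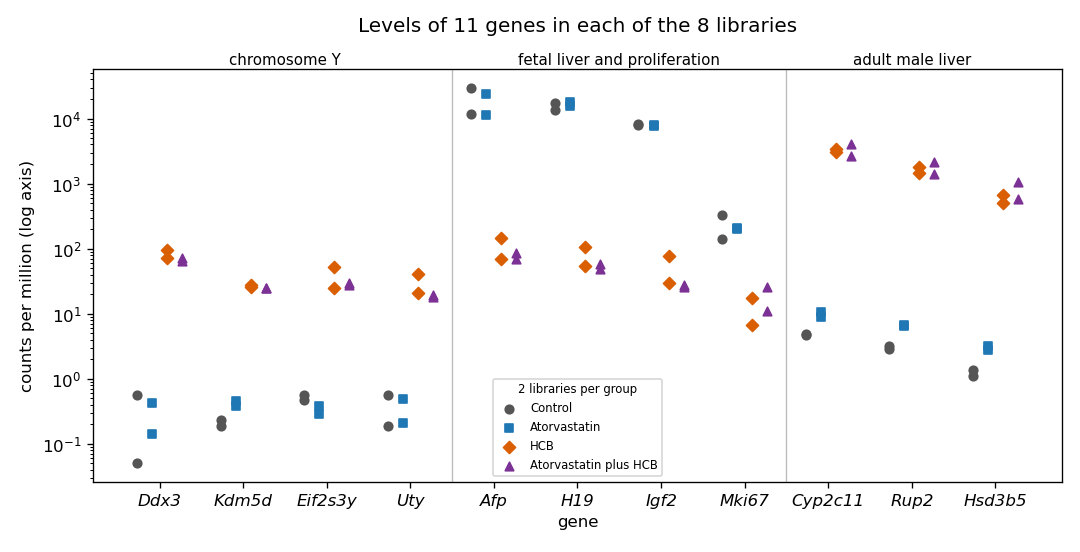
Level of 11 genes in each of the 8 libraries, in CPM on a log axis, with Y-linked, fetal or proliferation, and male-predominant genes apart and 1 point per library. The Y-linked gene Ddx3 averaged 76.1 CPM in the 4 HCB-labelled libraries and 0.291 CPM in the other 4.

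The comparison of HCB with control was meant to ask what exposure changed in the liver. An effect of HCB cannot be separated here from the difference in Y-linked and fetal liver genes. The libraries labelled HCB had far more of the genes of adult male rat liver. Cyp2c11 (ENSRNOG00000052810, chromosome 1, 236762842 to 236799066), the main cytochrome P450 of adult male rats, was at 3280.4 ± 227 CPM (SD, n = 2) against 4.79 ± 0.0802 CPM in control, a log2 fold change of 9.42 ± 0.49 (SE; edgeR adjusted p = 1.1e-06). Rup2 rose by 9.08 ± 0.46 and Hsd3b5, a steroid dehydrogenase of male liver, by 8.89 ± 0.48 on the log2 scale. Cyp2a2, a steroid hydroxylase, rose from 6.65 to 792 CPM. Of the 9 male-predominant genes tested, 8 rose over all genes and 9 adjusted over the list alone, and the gene that passed only adjusted over the list alone was Cyp3a2 (1.04, edgeR adjusted p = 0.074), named after its values were seen. Their median log2 change was 7.85, or 7.14 with Mup4 at its bound (camera adjusted p = 2.02e-31; adjusted p = 0.168 with an estimated correlation). Among the female-predominant genes 4 rose and 3 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.975; adjusted p = 0.983 with an estimated correlation), and their median and the camera direction were upward while fry's was downward.

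The genes that rose most included the pheromone carriers of the Mup cluster. Mup4 (chromosome 5, 74842319 to 75061474) was at least 141-fold higher in HCB than in control, where it had 0 reads, but its call was lost without Control replicate 1 (edgeR adjusted p = 0.0520). Its span overlaps Obp3 (chromosome 5, 74842316 to 74845757), which rose by 9.66 on the log2 scale, so reads of the pair are uncertain. Cyp2c24 was at least 123-fold higher, the pseudogene Mup4-ps3 at least 77.2-fold, Spin2b at least 57.5-fold and the citrate transporter Slc13a5 at least 56.4-fold. Dhrs7l1 rose by 10.01 ± 0.91 and Mup4-ps5 by 9.60 on the log2 scale. The copies of the Mup and Cyp2c families share reads, so the split between members is uncertain.

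Markers of preneoplastic foci were lower in HCB than in control in 11 of 21 cases, H19 and Igf2 among them. H19 (chromosome 1, 197730698 to 197733134), an imprinted noncoding RNA, averaged 15302 ± 2742 CPM (SD, n = 2) in control and 80.8 ± 38.3 CPM in HCB, a log2 change of −7.57 ± 0.58 (SE; edgeR adjusted p = 1.2e-05). Its neighbour Igf2 (chromosome 1, 197814410 to 197823018), a fetal growth factor, changed by −7.28 ± 0.58 and the trefoil peptide Tff3 by −8.84 ± 0.74. Akr7a3, an aldehyde reductase of the same list, rose by 5.98. Of the 21 focus markers tested, 3 rose and 11 fell over all genes, and 3 rose and 12 fell adjusted over the list alone (median −1.63; camera adjusted p = 1.99e-05; adjusted p = 0.528 with an estimated correlation). Gstp1, the usual marker of preneoplastic foci in rat liver, stood at 15.5 CPM in HCB and 14.6 CPM in control (log2 change 0.09 ± 0.32; edgeR adjusted p = 0.858).

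Cell cycle genes were lower in HCB. Mki67 (chromosome 1, 190496319 to 190522762), a marker of dividing cells, averaged 233 ± 130 CPM (SD, n = 2) in control and 11.9 ± 7.48 CPM in HCB (edgeR adjusted p = 0.000926). Cyclin A2 (Ccna2) changed by −4.04 ± 0.47, topoisomerase Top2a by −3.65 ± 0.43, the mitotic kinase Aurkb by −3.67 and the ubiquitin-conjugating enzyme Ube2c by −4.64 on the log2 scale. Of 29 cell cycle genes, 20 fell over all genes and 22 adjusted over the list alone (median −2.43; camera adjusted p = 6e-11; adjusted p = 0.641 with an estimated correlation). Of the TGF-beta and mesenchymal transition genes, 8 of 21 fell over all genes, Tgfb1 by 1.24 on the log2 scale among them, and 9 adjusted over the list alone (camera adjusted p = 0.0333; adjusted p = 0.677 with an estimated correlation). That list was no longer called without HCB replicate 2 (0.0507) or Control replicate 2 (0.0840).

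Blood lineage genes were also lower in HCB. The neutrophil granule gene Ngp averaged 66.7 CPM in control and 0.369 CPM in HCB (n = 2 each), a log2 change of −7.50 ± 0.39 (SE; edgeR adjusted p = 1.1e-06). The antimicrobial peptide Camp changed by −6.68 ± 0.45, S100a8 by −6.51 ± 0.51 and myeloperoxidase (Mpo) by −7.29, and all 10 neutrophil markers fell, over all genes and adjusted over the list alone. Their median was −6.60, or −5.83 with Elane at its bound (camera adjusted p = 9.47e-18; adjusted p = 0.311 with an estimated correlation). All 7 erythroid markers fell by both counts, over all genes and adjusted over the list alone, with a median of −2.24 (camera adjusted p = 8.66e-05; adjusted p = 0.624 with an estimated correlation). The hemoglobin chaperone Ahsp changed by −4.55 and the alpha globin Hba-a1, whose copies share reads, by −2.03 ± 0.48. The genes named for the largest falls were not all of blood lineages, and each had 0 reads in HCB. The microRNA gene Mir770 was at least 54.6-fold lower, the erythroid transcription factor Gfi1b at least 51.5-fold, the sodium channel subunit Scn3b at least 44.5-fold and the protease Pappa2 at least 40.3-fold. Elane, Stfa3, Pglyrp1 and Ctsg were at least 35.5, 31.9, 29.6 and 29.3-fold lower. The Mir770 call was lost without Control replicate 1 (edgeR adjusted p = 0.149), HCB replicate 1 (0.1002), HCB replicate 2 (0.0783) or Control replicate 2 (0.0637).

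Genes of foreign compound metabolism moved in both directions. Cyp1a2, a target of the aryl hydrocarbon receptor, averaged 962 CPM in HCB and 38.0 CPM in control (n = 2 each), a log2 change of 4.66 ± 0.51 (SE; edgeR adjusted p = 0.00013). Cyp2b1 (chromosome 1, 81518408 to 81542052), the phenobarbital-inducible P450, fell by 3.10 ± 0.81 on the log2 scale (edgeR adjusted p = 0.0223). Its call was lost without Control replicate 1 (0.139), Control replicate 2 (0.145), HCB replicate 1 (0.156), Atorvastatin replicate 1 (0.115) or Atorvastatin replicate 2 (0.130), and Cyp2b2 shares reads with it. Cyp1a1 had a log2 change of −1.56 ± 0.68 (edgeR adjusted p = 0.113) and was called without Atorvastatin replicate 1 (0.0389) or Atorvastatin replicate 2 (0.0421). Cyp3a23-3a1 had a change of 0.24 ± 0.36 (edgeR adjusted p = 0.644). Of the 19 targets of the receptors CAR and PXR, 10 rose and 3 fell over all genes, and 12 rose and 3 fell adjusted over the list alone (median 1.66; camera adjusted p = 5.53e-05; adjusted p = 0.638 with an estimated correlation). Cyp3a9 rose by 8.35 ± 0.57 and Cyp2c6v1 by 4.88, while Akr1b7 changed by −6.48 ± 0.54. Of 28 NRF2 and glutathione genes, 17 rose and 3 fell over all genes, and 19 rose and 3 fell adjusted over the list alone (camera adjusted p = 1.12e-06; adjusted p = 0.528 with an estimated correlation), with Gsta5 at 4.86 and Gsta3 at −2.92, members of a family that shares reads. Of 6 targets of the aryl hydrocarbon receptor 3 rose by both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.0343; adjusted p = 0.642 with an estimated correlation), a list call that was lost without Control replicate 1 (0.183).

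Heme synthesis, the pathway that HCB disturbs in porphyria, showed a rise of its first enzyme in HCB versus control. Alas1 averaged 390 CPM in HCB and 135 CPM in control (n = 2 each), a log2 change of 1.53 ± 0.32 (SE; edgeR adjusted p = 0.00603), and its call was lost without Control replicate 1 (0.0658). In the combination versus atorvastatin Alas1 had a change of 0.85 ± 0.32 (edgeR adjusted p = 0.0682; called without Atorvastatin replicate 2, 0.0203, and by DESeq2, 0.0297), and in the combination versus control of 0.84 ± 0.32 (edgeR adjusted p = 0.0738), with an interaction of −0.68 ± 0.45 (adjusted p = 1). Urod, the uroporphyrinogen decarboxylase, had a change of 0.11 ± 0.22 (edgeR adjusted p = 0.749) in HCB versus control. The heme list as a set was not called there (camera adjusted p = 0.418; adjusted p = 0.812 with an estimated correlation), with 3 members up and 1 down over all genes and 3 and 1 adjusted over the list alone.

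Part of the lipid synthesis genes were higher in HCB. Thrsp, a thyroid-responsive regulator of lipogenesis, averaged 924 CPM in HCB and 2.42 CPM in control (n = 2 each), a log2 change of 8.58 ± 0.56 (SE; edgeR adjusted p = 3.8e-06). Acetyl-CoA carboxylase Acacb rose by 3.10 ± 0.31, the malic enzyme Me1 by 2.83 and acetyl-CoA synthetase Acss2 by 3.40, and 10 of 18 fatty acid and triglyceride synthesis genes rose over all genes and 13 adjusted over the list alone (median 1.53; camera adjusted p = 3.23e-09; adjusted p = 0.528 with an estimated correlation). Of 25 cholesterol synthesis genes 11 rose over all genes and 12 adjusted over the list alone (median 1.00; camera adjusted p = 5.53e-05; adjusted p = 0.677 with an estimated correlation). The reductase Dhcr7 rose by 2.22 ± 0.44. The synthase Hmgcs1 had a change of 0.60 ± 0.39 (edgeR adjusted p = 0.280) and the epoxidase Sqle of 0.47 ± 0.36 (0.351). Cyp7a1 (chromosome 5, 19376974 to 19386688), the rate-limiting enzyme of bile acid synthesis, rose by 5.34 ± 0.85 (edgeR adjusted p = 0.00233), and 9 of 16 bile acid and sterol export genes rose and 1 fell over all genes, with 11 and 1 adjusted over the list alone (camera adjusted p = 1.92e-06; adjusted p = 0.528 with an estimated correlation).

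In all, edgeR called 4466 of 16591 genes between HCB and control, 2165 higher and 2301 lower, of which 1686 and 2003 changed at least 2-fold. Without Control replicate 1 the count was 2164, of which 2109 were among the 4466 genes, and without HCB replicate 1 it was 2595. Camera called 15 of the 36 lists, 10 upward and 5 downward, 0 of them with an estimated correlation (smallest adjusted p = 0.168 with an estimated correlation), and fry called 7. The acute phase list was called upward (camera adjusted p = 0.0312; adjusted p = 0.760 with an estimated correlation), with 7 members up and 3 down over all genes and 7 and 3 adjusted over the list alone. It came with Orm1 up by 6.26 ± 0.50 and Lbp changed by −2.10, and lost its call without Control replicate 1 (0.220). The thyroid hormone list (camera adjusted p = 0.0217; adjusted p = 0.528 with an estimated correlation) had 3 members up and 2 down over all genes and 5 and 2 adjusted over the list alone, and lost its call without Control replicate 1 as well (0.0661). The periportal list was called upward (camera adjusted p = 0.000475; adjusted p = 0.642 with an estimated correlation), 9 members up and 1 down over all genes and 9 and 1 adjusted over the list alone, with the urea cycle genes Arg1 and Ass1 up by 2.79 and 3.00.

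**Figure D2:**
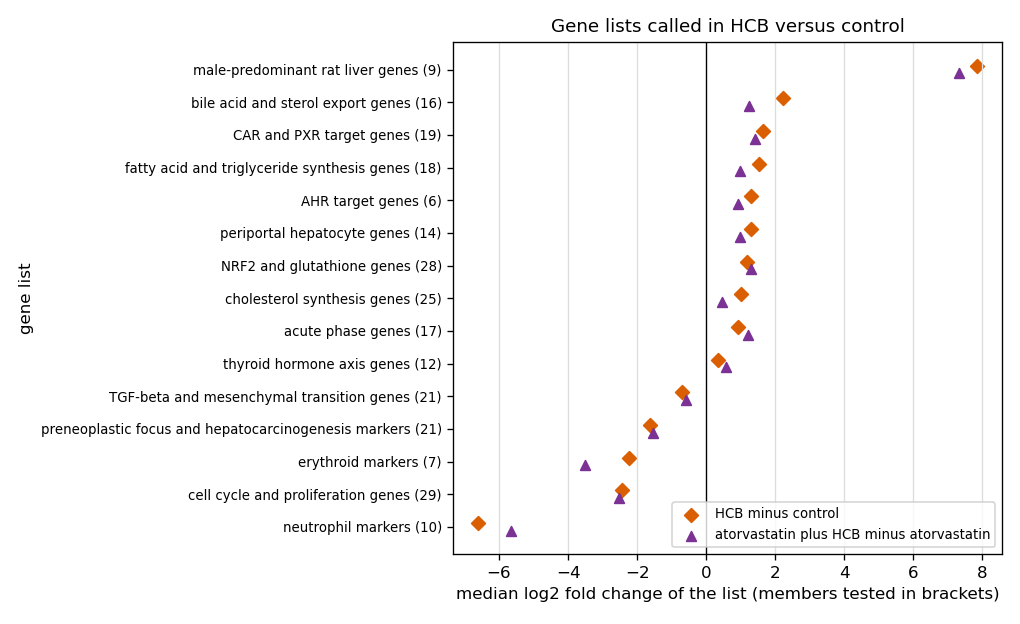
Median log2 fold change of the 15 gene lists called in HCB versus control, for that comparison and for atorvastatin plus HCB versus atorvastatin, with the number of members tested in brackets. The male-predominant list has medians of 7.85 and 7.33 and the neutrophil list medians of −6.60 and −5.65.

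The comparison of the combination with atorvastatin was meant to ask what HCB changed in treated rats. It shares no library with HCB against control but has the same limit, since its libraries also differ in Y-linked expression. Male-predominant genes were again higher, and cell cycle genes, H19, Igf2 and Ngp again lower, in the HCB-labelled libraries. Cyp2c11 averaged 3371 ± 1032 CPM (SD, n = 2) against 9.73 ± 1.14 CPM, a log2 change of 8.44 ± 0.47 (SE; edgeR adjusted p = 1.73e-06). H19 changed by −8.30 ± 0.60, Igf2 by −8.21 ± 0.61, Mki67 by −3.48 ± 0.59 and Ngp by −8.88, while Thrsp rose by 6.76 and Cyp1a2 by 4.64. Slc13a5 was at least 97.0-fold and Mup4 at least 85.6-fold higher, and the Mup4 call was lost without Atorvastatin replicate 1 (edgeR adjusted p = 0.0635) or Atorvastatin replicate 2 (0.0547). Cyp7a1 rose by 4.96 ± 0.84 (edgeR adjusted p = 0.00319; without Atorvastatin replicate 1, 0.0821; without Atorvastatin replicate 2, 0.0560). Cyp3a23-3a1 rose by 1.16 ± 0.36 (edgeR adjusted p = 0.0365) and lost its call without Atorvastatin replicate 1 (0.172), Atorvastatin plus HCB replicate 1 (0.150) or Atorvastatin plus HCB replicate 2 (0.101).

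Cell cycle genes fell in 23 of 29 cases over all genes and in 26 adjusted over the list alone (median −2.53; camera adjusted p = 7.75e-14; adjusted p = 0.525 with an estimated correlation). All 9 male-predominant genes rose by both counts, over all genes and adjusted over the list alone (median 7.33, or 7.32 with Mup4 at its bound; camera adjusted p = 4.95e-31; adjusted p = 0.159 with an estimated correlation). Of the 25 cholesterol synthesis genes 5 rose, among them Dhcr7 by 1.88, over all genes and adjusted over the list alone (camera adjusted p = 0.0242; adjusted p = 0.825 with an estimated correlation). That list was not called without Atorvastatin replicate 1 (0.359) or Atorvastatin plus HCB replicate 2 (0.0684). edgeR called 4571 genes, 2084 higher and 2487 lower. The count was 2629 without Atorvastatin replicate 1, 1902 without Atorvastatin plus HCB replicate 1 and 2504 without Atorvastatin plus HCB replicate 2.

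The HCB difference had the same sign with and without atorvastatin for nearly every called gene. Of the 4466 genes called in HCB versus control, 4451 had the same sign in treated rats, or 99.7% (95% exact binomial interval 99.4% to 99.8%, for counting genes as independent, which they are not). The slope of the log2 changes was 0.89. In the reverse direction 4545 of 4571 genes kept their sign, with a slope of 0.85. Both comparisons called 3293 genes with the same sign, where independent lists would share 617. Both also set libraries with Y-linked expression against libraries nearly without it, a difference that could give shared signs whatever HCB did. The shared signs therefore do not show that an effect of HCB was repeated. Across all 16591 genes the Pearson correlation was 0.856. The share ranged from 97.3% without HCB replicate 2 to 99.7% without Control replicate 2. Averaged over both strata, edgeR called 7728 genes, 3530 higher and 4198 lower in HCB-labelled libraries, with Cyp2c11 at 8.93 ± 0.34 and Mki67 at −3.88 ± 0.42.

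**Figure D3:**
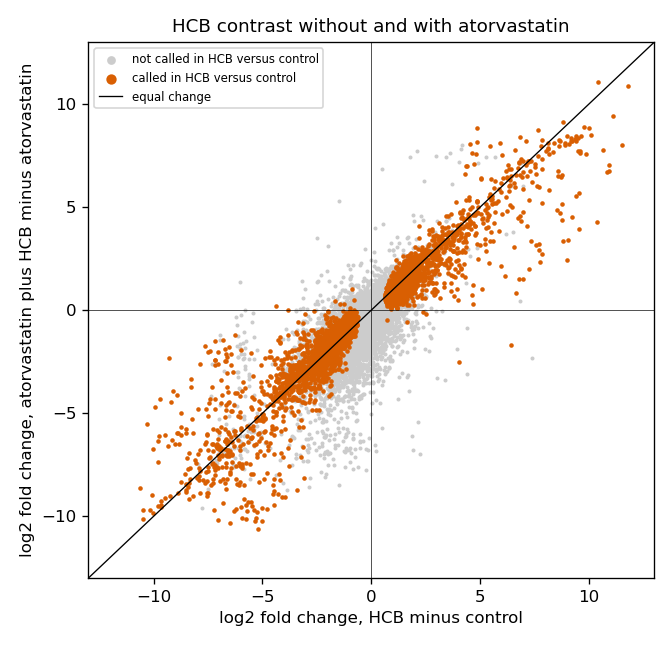
Log2 fold change of HCB versus control (horizontal) against atorvastatin plus HCB versus atorvastatin (vertical), 1 point per gene, with called genes coloured and the line of equality. Of the 4466 genes called in the first comparison, 4451 had the same sign in the second.

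The comparison of the combination with control asks whether treated, exposed liver returns to the control level, and it shares the control libraries with HCB versus control. It cannot settle this, since the control libraries also differ in Y-linked and fetal liver genes. Ugt2b, a glucuronosyltransferase, averaged 3485 CPM in the combination and 4.24 CPM in control (n = 2 each), a log2 change of 9.68 (edgeR). Cyp2c24 was at least 173-fold, Slc13a5 at least 88.0-fold and Mup4 at least 77.7-fold higher. The erythroid factors Gfi1b and Gata1 were at least 62.9-fold and 58.9-fold lower, and the myeloid gene Ms4a3 at least 52.9-fold lower. Mki67 changed by −3.65 ± 0.59 (SE; edgeR adjusted p = 0.002), Cyp1a2 by 4.92 and Cyp7a1 by 4.07 ± 0.80. Sqle had a log2 change of −0.08 ± 0.36 (edgeR adjusted p = 0.888). edgeR called 4252 genes, 1998 higher and 2254 lower. Without Control replicate 1 the count was 2090, without Atorvastatin plus HCB replicate 1 it was 1808, and without Atorvastatin plus HCB replicate 2 it was 2367.

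Atorvastatin against control asks what the statin changed in unexposed liver, provided that its libraries come from the rats the labels describe. No gene passed edgeR's adjusted threshold. The cholesterol synthesis gene Sqle averaged 90.1 ± 41.1 CPM (SD, n = 2) with atorvastatin and 81.7 ± 27.5 CPM in control, a log2 change of 0.14 ± 0.36 (SE), and Hmgcs1 had a change of 0.11 ± 0.39. edgeR called 0 of 16591 genes (smallest adjusted p = 1), with 181 at an unadjusted p under 0.05. Without a filter on low counts edgeR called 76 of 22537 genes, 57 higher and 19 lower. DESeq2 called 2, ENSRNOG00000066867 at 3.43 and Ugt2b at 1.33 on the log2 scale. In the control and atorvastatin libraries Ugt2b averaged 0.228% of its level in the HCB-labelled libraries. At such a trace level, reads carried over between libraries may account for part of its counts. The 5 smallest p by edgeR belonged to the cadherin gene Cdh11 (1.56 ± 0.30), ENSRNOG00000066867 (3.42 ± 0.70), Pbld1 (−1.13 ± 0.24), the secretoglobin Scgb1a1 (−1.87 ± 0.43) and the liver glycogen synthase Gys2 (−1.08 ± 0.26). Without Atorvastatin replicate 1 the count was 33, among them Scgb1a1 (−2.63, edgeR adjusted p = 0.0404), Fads2, the collagen gene Col1a1 and the adipocyte genes Adipoq (0.0305) and Plin1 (0.0102), the last 2 chosen after their values were seen. Among these, the DESeq2 call of Ugt2b was singled out after its value was seen. The desaturase Fads2 averaged 834 ± 830 CPM (SD, n = 2) with atorvastatin against 188 ± 80.9 CPM. Without Atorvastatin replicate 1 the atorvastatin group is Atorvastatin replicate 2 alone, in which Col1a1 was higher than in every other unexposed library. The calls of that fit therefore cannot be told from a trait of that single library.

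Camera called 12 lists between atorvastatin and control, 6 up and 6 down, but 0 with an estimated correlation and 0 by fry, and each of the 12 calls was lost or reversed without at least 1 library. Without Atorvastatin replicate 1 camera called 9 lists. The fatty acid and triglyceride synthesis list was called upward (camera adjusted p = 1.01e-10; adjusted p = 0.742 with an estimated correlation), led by Fads2 (2.15 ± 0.68) and Fads1 (1.79 ± 0.60), and was not called without Atorvastatin replicate 2 (0.755). The adipocyte markers were called upward as well (camera adjusted p = 9.37e-05; adjusted p = 0.742 with an estimated correlation), and not without the same library (0.357). The stellate cell and fibroblast markers were called upward too (camera adjusted p = 0.00104; adjusted p = 0.761 with an estimated correlation), were not called without Control replicate 1 (0.321), and were called downward without Atorvastatin replicate 2 (0.0460). The cholesterol synthesis list was called upward (camera adjusted p = 0.000951; adjusted p = 0.837 with an estimated correlation). It was not called without Control replicate 1 (0.818) and was called downward without Atorvastatin replicate 2 (0.00944). The mitochondrially encoded genes were called downward (camera adjusted p = 5.26e-12; adjusted p = 0.742 with an estimated correlation), but not without Atorvastatin replicate 1 (0.297). In these lists 0 members passed over all genes by edgeR, and 0 adjusted over the list alone apart from 1 adipocyte marker.

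The comparison of the combination with HCB asks what atorvastatin changed in exposed liver, the question of the study's title. No gene of cholesterol synthesis, the pathway that statins block, passed the test. Sqle averaged 77.2 ± 24.9 CPM (SD, n = 2) in the combination and 113 ± 7.30 CPM in HCB, a log2 change of −0.56 ± 0.36 (SE; edgeR adjusted p = 0.892). Hmgcs1 had a change of −0.27 ± 0.39 (edgeR adjusted p = 0.934). The cholesterol list was not called (camera adjusted p = 0.0897; adjusted p = 0.905 with an estimated correlation), with 0 members past edgeR's test over all genes or adjusted over the list alone. It was called without HCB replicate 1 (0.0112) or Atorvastatin plus HCB replicate 2 (0.0372). Atp2b2 (chromosome 4, 146896332 to 147140665), a plasma membrane calcium pump, averaged 40.8 ± 9.75 CPM (SD, n = 2) against 8.69 ± 0.738 CPM, a log2 change of 2.23 ± 0.26 (SE; edgeR adjusted p = 0.0501). It passed without Atorvastatin replicate 1 (0.0180), Atorvastatin replicate 2 (0.0158) or Atorvastatin plus HCB replicate 2 (0.0168). The zinc finger gene Zfp354a had a change of −2.58 ± 0.35 (edgeR adjusted p = 0.115). The remaining genes of smallest p were Efr3b, with 0 reads in HCB, ENSRNOG00000064437 (1.84) and the kinase gene Nim1k (2.19 ± 0.41), with edgeR adjusted p of 0.539 for Efr3b and Nim1k.

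In this comparison edgeR called 0 of 16591 genes, with 857 at an unadjusted p under 0.05, and DESeq2 called 49, of which 27 were higher and 22 lower, Atp2b2 (DESeq2 adjusted p = 3.96e-10) and Zfp354a (1.45e-08) among them. Without a filter on low counts edgeR called 179 of 22537 genes, 83 higher and 96 lower. Without HCB replicate 2 the edgeR count was 6, including the clock gene Bmal1, and without Atorvastatin plus HCB replicate 2 it was 6, including Per3 and Npas2. Bmal1 and Per3 were named after their values were seen. Without Atorvastatin replicate 1 or Atorvastatin replicate 2 it was 1, Atp2b2. Genes of the circadian clock made up the list with most members past the test adjusted over the list alone, 3 up and 6 down, with 0 over all genes by edgeR. Dbp averaged 5.38 CPM against 53.5 ± 39.5 CPM (SD, n = 2) in HCB (log2 change −3.31 ± 0.70), Npas2 had a change of 4.62 ± 1.05 and Bmal1 of 2.50. The clock list was not called (camera adjusted p = 0.0536; adjusted p = 0.905 with an estimated correlation). It was called without Control replicate 1 (0.0396), Control replicate 2 (0.0411), HCB replicate 1 (0.0108) or Atorvastatin plus HCB replicate 2 (0.0012). The erythroid list was called downward (median −1.56; camera adjusted p = 3.79e-09; adjusted p = 0.905 with an estimated correlation), with 0 members over all genes and 5 adjusted over the list alone, led by Hba-a3 (−1.32) and Alas2 (−1.81 ± 0.52). Camera called 7 lists, 4 up and 3 down, of which those other than the erythroid list lost their call without at least 1 library, and 14 without Atorvastatin plus HCB replicate 1. With an estimated correlation 0 lists were called, and by fry 0.

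The interaction asks whether the HCB difference depends on atorvastatin. No gene passed, and Thrsp had an interaction of −1.81 ± 0.59 (SE) on the log2 scale and the sterol exporter Abcg5 of −2.45 ± 0.59 (edgeR adjusted p = 1 for each). edgeR called 0 of 16591 genes (smallest adjusted p = 0.784), with 391 at an unadjusted p under 0.05. Without a filter on low counts edgeR called 70 genes, 19 higher and 51 lower. DESeq2 called 5: Nim1k at 2.88, Atp2b2 at 2.25, titin (Ttn) at −3.72, Zfp354a at −2.47 and ENSRNOG00000066867 at −3.95. Ttn was chosen after its values were seen. A fit without Atorvastatin replicate 1 has Atorvastatin replicate 2 as the only library of its group, so its calls cannot be told from a trait of that library. Without Atorvastatin replicate 1 edgeR called 5 genes, Fndc1, Sema3c, Ttn, Abcg5 and Ntrk2, of which those other than Abcg5 were also chosen after their values were seen.

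The control libraries differ from the HCB libraries in Y-linked and fetal liver genes, so they are not a plain unexposed baseline. A move toward them cannot be read as a return to the unexposed state. Within that limit, movement toward the control level was read from the correlation of HCB versus control with the combination versus HCB. These comparisons share the HCB libraries with opposite sign, so a negative value arises without any effect. Over 16591 genes Pearson's r was −0.14 and the covariance −0.222. Simulated groups with the HCB difference and no atorvastatin effect gave a mean r of −0.20 and a covariance of −0.253 (range −0.288 to −0.226 over 20 draws). The share of genes with opposite signs was 58.6% against a simulated 56.7% (55.2% to 57.6%). The draws vary each gene independently, unlike genes of real libraries, so their ranges are too narrow to judge these values by. Among the 4466 called genes the covariance was −0.502 against a simulated −0.179 (−0.249 to −0.111). The share of opposite signs was 66.3% against a simulated 50.6% (46.4% to 52.2%). These genes were chosen on the shared libraries of the real data, and the draws kept them without choosing anew. Their values therefore cannot tell a reversal from that choice.

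Averaged over both HCB strata, the effect of atorvastatin had 0 genes called by edgeR (smallest adjusted p = 0.919), with 601 at an unadjusted p under 0.05. Without a filter on low counts edgeR called 140 genes, 76 higher and 64 lower. DESeq2 called 4: Scgb1a1 at −1.80, Atp2b2 at 1.10, the hematopoietic factor Nfe2 at −1.25, named after its value was seen, and Zfp354a at −1.35. Without Atorvastatin replicate 1 edgeR called 9 genes.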

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

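The tests of the 6 gene lists here were fixed before the libraries were compared, and the shares of unassigned reads were looked at only afterwards.

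For 6 lists camera set the interaction of HCB and atorvastatin apart from that of the other genes tested, with 2 libraries in each of the 4 groups. This ranks a list against other genes and does not show that its own HCB difference changed with atorvastatin. Cholesterol synthesis genes had an interaction median of −0.52 on the log2 scale (camera adjusted p = 0.00170; adjusted p = 0.902 with an estimated correlation) and lost the call without Control replicate 1 (0.165), HCB replicate 2 (0.177) or Atorvastatin replicate 2 (0.840). Fatty acid and triglyceride synthesis genes had a median of −0.54 (camera adjusted p = 0.00193; adjusted p = 0.902 with an estimated correlation) and lost it without Control replicate 1 (0.0906), HCB replicate 2 (0.383) or Atorvastatin replicate 2 (0.863). PPAR-alpha and fatty acid oxidation genes had a median of 0.30 (camera adjusted p = 0.00687; adjusted p = 0.902 with an estimated correlation) and lost it without HCB replicate 2 (0.0935) or Control replicate 2 (0.790). Oncogene and growth factor signalling genes had a median of 0.34 (camera adjusted p = 0.0167; adjusted p = 0.902 with an estimated correlation) and lost it without HCB replicate 1 (0.246), Control replicate 2 (0.0992), Atorvastatin replicate 2 (0.0694) or Atorvastatin plus HCB replicate 2 (0.0727). Endothelial markers had a median of 0.33 (camera adjusted p = 0.00538; adjusted p = 0.902 with an estimated correlation) and lost it without HCB replicate 2 (0.197) or Atorvastatin replicate 1 (0.334). Erythroid markers had a median of −0.92 (camera adjusted p = 0.0222; adjusted p = 0.902 with an estimated correlation) and lost it without Control replicate 1 (0.278), HCB replicate 1 (0.794), Atorvastatin replicate 1 (0.985) or Atorvastatin plus HCB replicate 1 (0.0547). By fry the adjusted p was 0.955 for each of these lists, so these calls rest on camera's preset correlation. Camera called 3 lists without HCB replicate 2, 10 without Atorvastatin plus HCB replicate 2, and 11 without Atorvastatin replicate 2 or Atorvastatin plus HCB replicate 1. Each of the 6 calls also depends on at least 2 single libraries. No biological or technical explanation was tested for them.

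A pair of values came from the reads that no comparison uses. In Atorvastatin replicate 1, 34.04% of the reads fell in no annotated exon, against 27.7% and 15.3% in the control libraries. In the same library 21.0% of the reads aligned to several places, against 20.3% and 13.2% in the control libraries. The lowest share of reads assigned to genes, 42.7%, was in this library, and Control replicate 1 had 49.4%. No explanation was tested for these shares. The counts of calls with both libraries left out are given with the other alternatives.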

How the results depend on the processing

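Leaving out both libraries with most reads outside exons, halving the counts, removing chromosome Y and the filter of the deposited readme were tests chosen only after the results were seen. The lone library of a group left with 1 was assumed to vary like the other groups.

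DESeq2 size factors, the stricter filter, non-robust estimation and halved counts left each of the 8 counts of genes within 1.5 times the reported one, and 0 stayed 0. The libraries of 2 groups alone did so for the 5 comparisons of 2 groups, the ones it can be run on. In HCB versus control these counts ran from 4089 to 4508. Without a filter on low counts, edgeR called 76 genes in atorvastatin versus control, 179 in the combination versus HCB, 70 in the interaction and 140 in the atorvastatin average. DESeq2 called 2, 49, 5 and 4. With the readme filter the counts were 1815 in HCB versus control, 1 in atorvastatin versus control, 18 in the combination versus HCB, 1991 in the combination versus control, 2175 in the combination versus atorvastatin, 5 in the interaction, 2404 in the HCB average and 1 in the atorvastatin average. That setting asks for a larger change by construction. With both libraries out, fewer samples gave 2108, 2015, 2147 and 4643 in HCB versus control, the combination versus control, the combination versus atorvastatin and the HCB average, and a same-sign share of 99.0%. For the differences without a stated construction, the cause was not tested.

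Leaving out 1 library at a time gave 2164 to 4622 genes in HCB versus control, 0 to 33 in atorvastatin versus control, 0 to 6 in the combination versus HCB, 1808 to 4526 in the combination versus control, 1902 to 4819 in the combination versus atorvastatin, 0 to 5 in the interaction, 5813 to 7464 in the HCB average and 0 to 9 in the atorvastatin average. The same-sign share ran from 97.3% to 99.7%. Lists called by camera ran from 12 to 17 in HCB versus control, 9 to 16 in atorvastatin versus control, 7 to 14 in the combination versus HCB, 15 to 17 in the combination versus atorvastatin and 3 to 11 in the interaction. With an estimated correlation 0 lists were called in each of these 5 comparisons, and fry called 7, 0, 0, 4 and 0. The reversal correlation over all genes was −0.14, where the simulation without an atorvastatin effect gave −0.20. Over called genes only it was −0.20 against a simulated −0.10. The called genes were chosen on the shared HCB libraries and the draws did not choose anew, so that pair is not a like comparison.

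In all, 3 list results were called in the reported test and, with the opposite direction, in an alternative. A turn of direction was counted only where both results were called. For the list cell cycle and proliferation genes, Atorvastatin versus control, the direction turned without Control replicate 1 (1.43e-05), in a range of camera adjusted p from 2.04e-24 to 0.533. The list cholesterol synthesis genes, Atorvastatin versus control, turned without Atorvastatin replicate 2 (0.00944; range 2.40e-14 to 0.818), and so did the list stellate cell and fibroblast markers, Atorvastatin versus control (0.0460; range 2.86e-20 to 0.321). The cause was not tested. Of the remaining list results 1709 kept their side of the threshold, 102 gained and 166 lost a call. Of the named gene results 1243 kept their side of the threshold, 19 gained and 25 lost a call. A result called in neither setting was counted as kept whatever its direction.

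The replicate numbers do not pair the libraries over all groups: deviations of same-numbered libraries correlated at −0.05 to 0.05 across genes, apart from 0.27 between control and atorvastatin. In these 2 groups replicate 1 also had more reads in no annotated exon (27.7% and 34.04%) than replicate 2 (15.3% and 19.5%). The block is 1 effect over all 8 libraries, so it does not model a difference confined to these groups. With the replicate number as a block, 4282 genes were called in HCB versus control, 0 in atorvastatin versus control, 0 in the combination versus HCB, 4163 in the combination versus control, 4398 in the combination versus atorvastatin, 0 in the interaction, 7548 in the HCB average and 0 in the atorvastatin average, and the same-sign share was 99.7%. The block brought calls of Cyp1a1 in HCB versus control (0.0239), of cholesterol synthesis (0.0377) and TGF-beta genes (0.0379) in the combination versus HCB, and of cell cycle genes in the interaction (0.0292), and changed no other call of a named gene or list. Of the 4466 genes of HCB versus control 4125 were among those called with the block, of the 4252 of the combination versus control 3985, of the 4571 of the combination versus atorvastatin 4223, and of the 7728 of the HCB average 7385. Block list counts were 15, 12, 9, 16 and 7 in the order above.

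With 2 libraries per group, simulated 2-fold changes were mostly missed at this depth in comparisons of 2 groups. Of 100 such changes, 10 were recovered in atorvastatin versus control and 1 in the combination versus HCB. In the atorvastatin average 48 of 100 were recovered, and the interaction was not simulated. The counts of 0 therefore do not exclude changes of that size.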

Other observations

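The tests of Y-linked levels, of exchanged labels and of reads carried over were chosen only after the result was seen, while those of Cyp2c12, of imprinted genes and of other splits of the libraries were written before their values were seen.

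The control and atorvastatin libraries stand apart from both HCB groups in Y-linked and fetal liver genes, although the labels call every rat male. Exposure of male rats to HCB is excluded as the whole source of the difference: the median level of Y-linked genes in the unexposed libraries was 1.24% of that in the HCB libraries, and unexposed males carry these genes. An exchange of labels within the series is excluded as the whole source as well, since 4 libraries lie under 10% of the highest in median Y-linked level (0.408% to 1.20%), and no exchange makes all 8 male. An exchange between HCB and unexposed labels on top of another source, which would turn every HCB direction, stays open. Liver of adult females would need Cyp2c12, the P450 of adult female rats, at least 10-fold higher, and its mean in the unexposed libraries was 0.0380 times that in the HCB libraries (7.90 to 23.0 CPM against 161 to 806 CPM). The bound written beforehand, under 10 CPM in every such library, was not met in Control replicate 2 (14.8 CPM) and Atorvastatin replicate 2 (23.0 CPM), and the source of these low levels was not tested. Of 8 imprinted growth genes measured, 7 were at least 2-fold higher in the unexposed libraries, Grb10 57.1-fold, Plagl1 43.6-fold and Mest 21.4-fold among them, with Igf2r at 1.72-fold. A candidate explanation is therefore that these 4 libraries came from fetal or newborn liver without a Y chromosome, for which no test of age beyond the imprinted genes was run. A wrong label or a swap with libraries from outside the series needs no partner here and stays open. An effect of HCB itself cannot be separated from this difference in any comparison of HCB-labelled with unexposed libraries. The comparisons within the HCB-labelled pair and within the unexposed pair do not cross it. Atorvastatin versus control still rests wholly on the libraries of uncertain source. Whether it measures the statin in rats as labelled cannot be told. The interaction and the average effect of atorvastatin use both sets of libraries and share this limit.

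Genes that were abundant in one set of libraries left traces in the other. Of 130 genes at 1000 CPM or more in the HCB-labelled libraries and 65 in the unexposed ones, 0 lay under 0.1% of that level in the other set, and the lowest were at 0.209% and 0.418%. Afp, H19 and Igf2 stood at 0.307% to 0.441% of their unexposed level in HCB replicate 2 and both libraries of the combination, and at 0.672% to 0.940% in HCB replicate 1. The count of 0 is what reads carried over between libraries of one pool require, so carry-over may account for part of the low levels. Real low expression would give the same traces for single genes and stays open.

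Other splits of the 8 libraries into 4 and 4 were counted with a model of 2 groups. Of the 35 splits, 1 gave as many genes as the split by HCB, namely that split itself, with 8208 genes against 1 gene in the highest of the others. The first principal component, with 72.1% of the variance, followed the HCB label. The other splits leave that difference in their spread and can hardly call a gene. Their low counts therefore do not exclude chance for the split by HCB. The split by atorvastatin gave 0 genes, a count that any split reaches, so the 35 splits say nothing about chance for it. The highest of the others there, with 8208 genes, is the split by HCB, a structure of the samples.

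A few genes of collagen, elastic fibre and smooth muscle, chosen after their values were seen, were higher in Atorvastatin replicate 2 than in the other unexposed libraries, and no list of such genes was tested on that library alone. Col1a1 was at 1351 CPM there and at 136, 138 and 152 CPM in the others. Elastin (Eln) was at 304 CPM against 23.4 to 73.4 CPM, and the smooth muscle myosin Myh11 at 24.6 CPM against 2.99 to 3.83 CPM. Albumin (Alb) was between 45740 and 124965 CPM in all 8 libraries.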
